A study of Mus musculus with 12 samples.

How the data were processed

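RNA from islets isolated by collagenase digestion and a density gradient was hybridised to Illumina mouse bead arrays, 1 array per mouse, 6 SRI-tg10 and 6 control. The deposited signal table gives an intensity, the mean bead signal on a linear scale, for each probe and array, per the file headers, and GenomeStudio is named in the submitters' processing notes with no version. The same deposited table gives a detection p-value for each probe and array, per the file headers. A second deposited table holds the authors' processed values on a log2 scale, whose centring and background treatment are not given in the sources used here. The authors' deposited table of the comparison gives log2 fold changes, a t score, p-values and q-values, per the file headers. The genome build is not given in the sources used here.

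Groups were taken from the source labels, and replicate numbers follow accession order and pair no samples. The main values were computed from the raw signals with limma 3.58.1 in R 4.3.3: normexp background correction from the detection p-values, an offset of 16, quantile normalization between arrays and log2. Probes with a detection p under 0.05 on at least 6 arrays were tested (18315 of 45281). Each probe was fitted with genotype alone (lmFit and eBayes), two-sided, with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. Probe names were updated through the Entrez IDs in the authors' deposited table for 21860 probes and through symbols and synonyms of the RefSeq annotation of GRCm38.p6 for 9331 and 5493 probes, and 8597 kept the symbol of the file. A gene is shown by its brightest tested probe.

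Lists of genes for pathways and cell types, 34 in all, were fixed before the data were examined, as were the groups, the tests and most of the other settings. All but the sex check list (33) were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, which tests a list on its own. The genes named in the text were chosen by a rule fixed at the same time: every Sri probe, up to 12 passing genes per direction by fold, genes with the smallest p to make up 6 per direction, up to 4 members of each list by p, and 24 genes named beforehand. Genes taken by fold or to make up 6 also had to have all 6 SRI-tg10 arrays on the same side of the control mean. Some genes that this rule takes are not reported here and were left out of the search for single arrays that stand apart. Sri probes also had a two-sided exact permutation test.

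The fit was tested on simulated arrays with the means and spreads of the 18315 probes, 200 of them changed. In 1 simulation it called 148 probes, 6 of them unchanged, and recovered 31.3% of changes of 1.5-fold, 83.6% of 2-fold and 98.5% of 4-fold. The adjustment was less strict with 148 passing probes than with the 4 that passed in the real comparison. These shares therefore do not carry over to the real comparison, where fewer such changes would pass. A list shifted by 0.3 on the log2 scale was found, and no other simulated list was called. The simulated probes varied independently and the lists were random. This cannot show how often lists of genes that vary together are called without a shift, such as the macrophage markers (estimated correlation 0.731). Array weights used statmod 1.5.0. Alternatives covered the background correction, scaling, probe filter, title letter, variance model, array weights, acinar content, each array left out in turn and the authors' processed values. Slide could not be used as a block because the column names give no barcode.

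Each column of the authors' processed values was compared with the raw signals of every array over probes with a mean log2 value above 8. The column under an array's own accession correlated best with that array in 2 of 12 cases, and the comparison here rests on the raw signals, as fixed beforehand. These values were used as deposited in a setting chosen beforehand, and with columns matched to arrays in an alternative added after seeing the data. Medians of the 12 columns ran from 5.70 to 5.90 on the log2 scale.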

Results

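Islet RNA from 12 male C57BL/6 mice was measured on Illumina bead arrays with 45281 probes. The mice were 8 weeks old, and 6 of them carried 10 copies of an inducible sorcin transgene (SRI-tg10) while 6 were littermate controls. Sorcin, the product of Sri, is a calcium-binding protein of the penta-EF-hand family, and the transgene was switched on in beta cells by doxycycline through a transactivator under the rat insulin promoter. All animals had eaten a diet with 60% fat and drunk 500 mg/L doxycycline for 4 weeks. The labels give each array its own mouse number, so the spread between arrays includes that between animals. Mean raw signal per array ran from 328 to 622 and the number of detected probes from 16271 to 20094, with the lowest value of both on control replicate 5. The number of arrays limits the precision: the median standard error of a log2 fold change was 0.179, over 18315 tested probes for 12279 genes.

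Sri rose in SRI-tg10 islets at each of its 3 tested probes, and every SRI-tg10 array lay above every control array. At the brightest probe (ILMN_2600537) the normalized signal was 9.86 ± 0.22 in controls and 14.53 ± 0.89 in SRI-tg10 islets on the log2 scale (SD, n = 6 each), a log2 fold change of 4.67 (95% confidence interval 3.96 to 5.38, limma adjusted p = 1.53e-05). The other 2 probes gave log2 fold changes of 4.12 (ILMN_3120014, SE 0.26) and 5.21 (ILMN_3044633, SE 0.50). A two-sided exact permutation test of each of these probes gave p = 0.00216, the smallest value that 924 arrangements allow. Another Sri probe (ILMN_2704048) was detected on 2 arrays and was not tested. SRI-tg10 replicate 4 had a lower Sri level than the remaining SRI-tg10 arrays, with 12.72 at the brightest probe against at least 14.81 on each of the others. With title letter B alone, 3 arrays against 3 and replicate 4 among them, the log2 fold change was 4.30 and the limma adjusted p was 0.883, against 5.04 and 8.73e-05 with letter A alone.

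**Figure D1:**
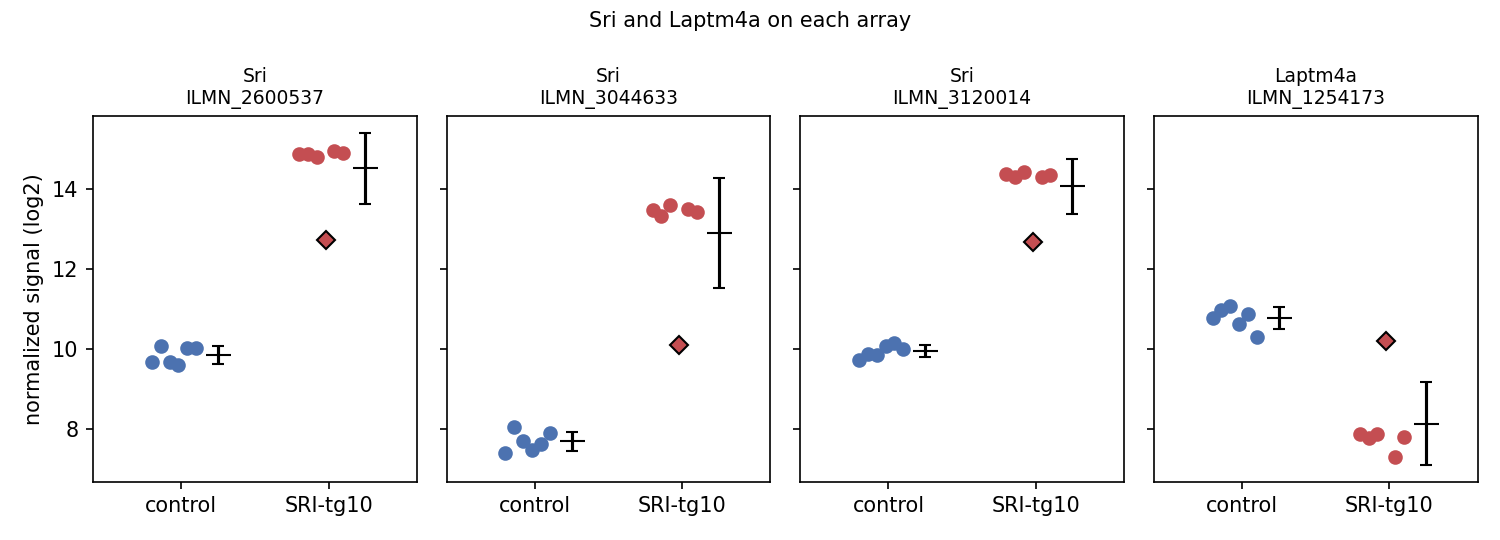
Normalized log2 signal (vertical axis) of 3 Sri probes and the Laptm4a probe on each array (horizontal axis, by group), with points for arrays and bars for the mean ± SD of 6 arrays. SRI-tg10 replicate 4, drawn as a diamond, reached 12.72 at Sri probe ILMN_2600537 and 10.21 at Laptm4a, between the other SRI-tg10 arrays and the controls.

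Apart from Sri, a single gene passed the test over all tested probes. Laptm4a, which encodes a lysosome-associated transmembrane protein, fell in SRI-tg10 islets from 10.78 ± 0.28 to 8.14 ± 1.04 on the log2 scale (SD, n = 6 each), a log2 fold change of -2.65 with a 95% confidence interval of -3.48 to -1.81 (limma adjusted p = 0.0434). Every SRI-tg10 array lay below every control array, at most 10.21 against at least 10.30 (two-sided exact permutation p = 0.00216). Laptm4a has 1 probe on the array. In the adjustment over probes the 3 Sri probes rank ahead of it. With each gene counted once, by its brightest probe, only Sri passed. The call for Laptm4a was kept without SRI-tg10 replicate 4 (limma adjusted p = 6.84e-07) and lost on leaving out any other array in turn (11 cases, adjusted p up to 0.181), while the log2 fold change stayed between -3.06 and -2.48. Over 26 alternatives the adjusted p of Laptm4a ran from 4.85e-08 to 0.999. The highest came from the authors' processed values by their deposited headers (log2 fold change 0.31). With columns matched to arrays these values gave -2.535 (limma adjusted p = 0.0241). Title letter B alone gave a limma adjusted p of 0.884.

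In all, 4 of 18315 probes passed an adjusted p of 0.05, the 3 Sri probes higher and the Laptm4a probe lower. At an unadjusted p under 0.05 there were 781 probes, 337 higher and 444 lower, where 916 would be expected by chance. The nearest probe that did not pass was 1 of 2 for Abraxas2, a scaffold subunit of the BRISC deubiquitinase complex, with a log2 fold change of 0.87 (limma adjusted p = 0.0530). It was above the control mean in 6 of 6 SRI-tg10 arrays but detected in 3 of 6 controls, and the brighter Abraxas2 probe gave -0.15. The dimmer probe passed without SRI-tg10 replicate 5 (log2 fold change 0.95, limma adjusted p = 0.0280) and with array weights (0.79, adjusted p = 0.0359). Among the next genes by p that the rule took, none of which passed, were Cbx1, a heterochromatin protein, higher by sign but detected in 1 of 6 controls, and Gna13, a G protein alpha subunit, with 0.51 at a dim probe and 0.06 at its brighter probe. On the lower side were Piga, needed for the synthesis of GPI anchors, with -0.84, Rgcc, a regulator of the cell cycle, with -0.71, and Bend6 with -0.55. Bend6 was near the detection limit in both groups (means of 5.57 and 5.02), and was detected in 6 of 6 controls and 0 of 6 SRI-tg10 arrays. The rule took only genes with all 6 SRI-tg10 arrays on the same side of the control mean, Abraxas2 among them. That trait is therefore no evidence beyond the p-values.

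Beta cell hormones and identity genes showed no difference that passed the test. Ins1 and Ins2, which encode the 2 mouse insulins, Gcg (glucagon) and Sst (somatostatin) had log2 fold changes of -0.04, 0.01, -0.01 and -0.05. Their probes read between 14.34 and 15.17 on every array, where 15.17 is the highest normalized value, and at this end of the scale such values do not show that hormone expression was unchanged. Ppy (pancreatic polypeptide), read between 13.61 and 14.83, had a log2 fold change of 0.24 (0.12 without control replicate 5, 0.40 without SRI-tg10 replicate 3). Of 16 tested beta cell transcription factors, 11 were higher and 5 lower by sign, with Pdx1 at 0.35 (SE 0.17), Nkx6-1 at 0.26 (0.07 without control replicate 5) and Mafa at -0.14 (0.15 at another probe, 0.05 without control replicate 2 and -0.26 without SRI-tg10 replicate 3). This list was called higher without SRI-tg10 replicate 3 (camera adjusted p = 0.0440) and with array weights (adjusted p = 0.0478), both with the preset correlation, and over all arrays it had adjusted p = 0.684 with an estimated correlation. G6pc2, the islet glucose-6-phosphatase, was 14.48 ± 0.17 in controls and 14.03 ± 0.28 in SRI-tg10 islets (SD, n = 6 each). Its log2 fold change of -0.45 did not pass (limma adjusted p = 0.922), although all 6 SRI-tg10 arrays lay below the control mean, and a dimmer G6pc2 probe gave -0.83. Iapp, which encodes the peptide co-secreted with insulin, had -0.37 and Slc2a2, the glucose transporter GLUT2, 0.04 (-0.06 without SRI-tg10 replicate 2, 0.14 without control replicate 5, and -0.23 at both of its other probes). In the list of insulin, granule and glucose sensing genes, 15 of 25 were lower by sign (camera adjusted p = 0.206), with a call lower without SRI-tg10 replicate 2 (adjusted p = 0.0244) or control replicate 5 (adjusted p = 0.0160). These calls used the preset correlation, and over all arrays this list had adjusted p = 0.837 with an estimated correlation.

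Most measured genes of endoplasmic reticulum folding and transport were lower by sign in SRI-tg10 islets, with list calls that did not hold with an estimated correlation. In the list of ATF6 targets and chaperones, 17 of 18 tested genes were lower, with a median log2 fold change of -0.16 (camera adjusted p = 0.00165 with a preset correlation, adjusted p = 0.684 with an estimated correlation). Dnajc3 and Creld2, co-chaperone and folding factor genes induced by unfolded proteins, had -0.43 and -0.38, Derl3 of the degradation pathway -0.59 (-0.39 without control replicate 3), Atf6 -0.24 (detected in 3 of 6 SRI-tg10 arrays) and Hspa5, the chaperone BiP, -0.16 (-0.04 without SRI-tg10 replicate 4, -0.28 without SRI-tg10 replicate 3). In the list of IRE1 and XBP1 targets, 16 of 19 were lower (camera adjusted p = 0.0285 with a preset correlation, adjusted p = 0.684 with an estimated correlation). Among them were Spcs3 of the signal peptidase with -0.42 and the co-chaperone Dnajb9 with -0.35, while Xbp1 itself had -0.02. No gene of either list passed the test, over all genes or adjusted over the list alone, and exact permutation tests of the list means per array gave p = 0.0714 and p = 0.128. Of 100 splits of the 12 arrays into 6 and 6, the genotype included, 90 shifted at least 3 lists, as many as genotype did with these lists and the macrophage markers. Relative to other genes the ATF6 list had a mean of -0.20 and the IRE1 list -0.14. The ATF6 list lost its call without control replicate 3 (-0.11, adjusted p = 0.212), and the IRE1 list without control replicate 1 (-0.13), control replicate 3 (-0.09) or SRI-tg10 replicate 4 (-0.11), at adjusted p up to 0.305. The PERK, ATF4 and CHOP list did not pass (camera adjusted p = 0.929), with a median of -0.01 and a mean of 0.02, Ddit3 (CHOP) at -0.17 (-0.10 without control replicate 1, -0.26 without SRI-tg10 replicate 1) and Trib3 at 0.11 (-0.03 without control replicate 6, 0.20 without SRI-tg10 replicate 2).

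Genes of immune cells varied widely between arrays of the same group. The macrophage markers were higher by sign in SRI-tg10 islets at all 21 tested genes, with a median of 0.25 (camera adjusted p = 0.0401), Mrc1 at 0.76 and Cd74 at 0.60 (0.28 without control replicate 5), and adjusted p = 0.837 with an estimated correlation. Their mean per array was 8.71 ± 0.75 in controls and 9.03 ± 0.58 in SRI-tg10 islets (SD, n = 6 each, log2 scale; two-sided exact permutation p = 0.374). The call was lost in 6 of 12 cases on leaving out an array in turn (control replicates 1, 3 and 4, SRI-tg10 replicates 3, 4 and 5), at adjusted p up to 0.448, and with the title letter as a block (adjusted p = 0.0751). The mean of the list relative to other genes, 0.30 over all arrays, ran from 0.18 without SRI-tg10 replicate 4 to 0.53 without control replicate 6. Lymphocyte markers were higher by sign at 13 of 16 genes (camera adjusted p = 0.150), with means of 7.74 ± 1.18 and 8.08 ± 1.57. Relative to other genes the lymphocyte list was lower by a mean of -0.63 in letter A alone and higher by 1.31 in letter B alone, a call in both (camera adjusted p = 0.0292 and 0.000271), and it was called higher in 5 of 12 cases on leaving out an array (adjusted p from 0.00304 to 0.0410) and with median scaling (adjusted p = 0.0183). These calls used the preset correlation, and over all arrays the list had adjusted p = 0.837 with an estimated correlation.

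**Figure D2:**
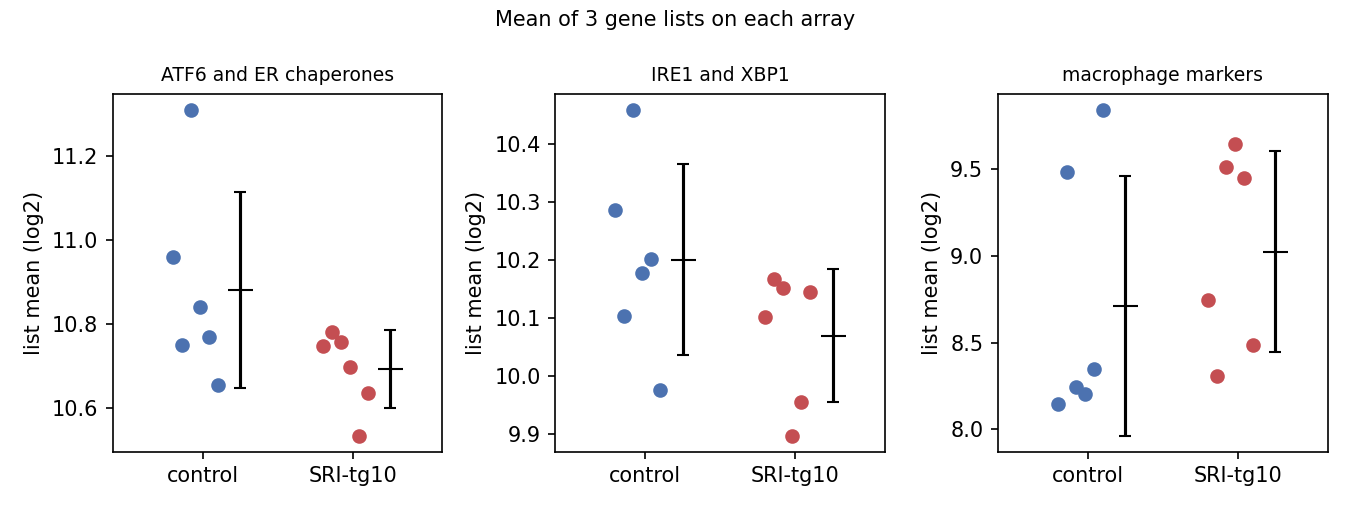
Mean log2 signal over the tested genes of 3 gene lists (vertical axes) on each array (horizontal axis, by group), with points for arrays and bars for the mean ± SD of 6 arrays. The mean of the ATF6 and chaperone list was 10.88 ± 0.23 in controls and 10.69 ± 0.09 in SRI-tg10 islets, with overlapping arrays.

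Calcium handling genes gave no call beyond Sri when adjusted over all tested probes. In the list of calcium stores and channels, 17 of 28 tested genes were higher and 11 lower by sign (camera adjusted p = 0.518). Itpr3, an inositol trisphosphate receptor, had a log2 fold change of 0.59 on the same side of the control mean in all 6 SRI-tg10 arrays, and did not pass. Atp2b4, a plasma membrane calcium pump, was lower by sign but detected in 5 of 6 controls and 2 of 6 SRI-tg10 arrays. The SERCA pump genes Atp2a2 and Atp2a3 had 0.11 and 0.04 (-0.07 and -0.10 at another probe of each). Without control replicate 5 they had 0.04 and -0.10, and Atp2a2 had 0.02 without SRI-tg10 replicate 2. Itpr1 had 0.09 at its brightest probe (0.01 without control replicate 3, 0.15 without SRI-tg10 replicate 4) and -1.11 at another. Ryr2, the ryanodine receptor with which sorcin is known to interact, was not detected on enough arrays to be tested. Among calcineurin and NFAT genes, Nfatc1 had 0.53 (0.29 without control replicate 5, and -0.26 at another probe), Nfatc2 -0.52 and Nfatc3 0.05, or -0.02 without SRI-tg10 replicate 5 (camera adjusted p = 0.713 for the list). In the penta-EF-hand list, 2 of 8 genes passed when adjusted over the list alone, Sri and Anxa11, an annexin with a log2 fold change of 0.43, and Sri passed over all genes. The list as a whole had a camera adjusted p of 0.150 and a median of 0.01. The camera adjusted p was 0.0346 with median scaling, 0.0381 with the stricter probe filter, 0.0403 in title letter A alone and 0.684 with an estimated correlation. It was the only list called by fry, in a single direction (adjusted p = 0.0248) and in either (adjusted p = 7.75e-05), and it contains Sri itself, while its other 7 members lay between -0.46 (Gca) and 0.43 (Anxa11). Without Sri in the list, an alternative chosen after seeing the data, fry gave adjusted p = 0.892 in a single direction and 0.881 in either.

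Markers of the remaining cell types did not pass as lists in the main fit, over all arrays and without array weights. Acinar markers were bright in both groups, at a list mean of 13.63 ± 0.35 in controls and 13.68 ± 0.23 in SRI-tg10 islets (SD, n = 6 each, log2 scale, camera adjusted p = 0.467). Some lay near the highest normalized value of 15.17, such as Cel (14.68 to 15.06) and Cela1 (14.52 to 14.90). Near-equal means therefore do not show that acinar content was equal. Endothelial markers (11 of 16 lower by sign) and alpha cell markers (5 of 7 lower) had camera adjusted p values of 0.150 and 0.365. The endothelial list was called lower without SRI-tg10 replicate 4 (mean relative to other genes -0.14, adjusted p = 0.0214), SRI-tg10 replicate 5 (-0.15, adjusted p = 0.00809) or control replicate 5 (-0.16, adjusted p = 0.00114), in each case with the preset correlation, and over all arrays it had adjusted p = 0.837 with an estimated correlation. Erythrocyte markers were higher by sign at all 6 tested genes (camera adjusted p = 0.467), and were called without control replicate 5 (adjusted p = 0.0109), with adjusted p = 0.842 with an estimated correlation over all arrays. Array weights, with the preset correlation, gave calls for the acinar (mean relative to other genes 0.20, adjusted p = 0.0160), endothelial (-0.23, adjusted p = 4.47e-05) and erythrocyte lists (0.76, adjusted p = 0.0160), and the acinar list had adjusted p = 0.861 with an estimated correlation. Title letter A alone, unweighted and with the preset correlation, also called the acinar (0.28, camera adjusted p = 0.0212) and endothelial lists (-0.24, adjusted p = 2.24e-05). It further called the erythrocyte (0.59, adjusted p = 0.0345) and Schwann cell and neuronal lists (-0.43, adjusted p = 0.0403). Letter B alone called none of these lists.

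Genes of metabolism did not pass as lists over all 12 arrays. Of 20 tested genes of glycolysis and hypoxia 16 were higher by sign (camera adjusted p = 0.163, and 0.0454 without control replicate 5, against adjusted p = 0.684 with an estimated correlation over all arrays), with Slc2a1, the glucose transporter GLUT1, at 0.27. Of 21 genes of fatty acid oxidation 14 were lower (camera adjusted p = 0.391), with Acadm, a medium-chain acyl-CoA dehydrogenase, at -0.18 and the nuclear receptor Ppard at 0.41 (-0.11 and 0.20 without control replicate 5). Of 33 genes of oxidative phosphorylation 19 were lower (camera adjusted p = 0.668). Lipogenic genes (12 of 17 higher) had a camera adjusted p of 0.365, with Acaca, acetyl-CoA carboxylase, at 0.27 and Txnip, a thioredoxin inhibitor induced by glucose, at -0.21 (-0.08 without control replicate 4).

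The authors' deposited table of fold changes lists 1577 probes at a p under 0.05 and 5 at a q value under 0.05. In the authors' deposited table these 5 are the 3 Sri probes, Laptm4a with a log2 fold change of -2.90 (q = 4.52e-08) and a probe of A130077B15Rik with 1.22 (q = 0.0169). Another A130077B15Rik probe had 0.05 there (q = 0.965), and was detected on 4 arrays and not tested here. The fit here gave A130077B15Rik 0.97 (SE 0.28, limma adjusted p = 0.922), above the control mean in 5 of 6 SRI-tg10 arrays. The exception was SRI-tg10 replicate 4, at 7.59 against at least 8.81 on the other SRI-tg10 arrays and 7.60 to 8.22 in controls. This gene was chosen after its values were seen. It passed here without SRI-tg10 replicate 4, when 5 probes were called. Across the 18315 shared probes, which are not independent replicates, the fold changes fitted here correlated with those in the authors' deposited table at Pearson r = 0.808 and Spearman rho = 0.824. The mean expression in the authors' deposited table equals the mean of the authors' processed values over 11 arrays, without SRI-tg10 replicate 4 and with columns matched to arrays, to within 5e-09.

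The array titles carry a letter, A or B, that the labels do not explain, with 3 control and 3 SRI-tg10 arrays under each. With genotype in the model, 17 probes differed between the letters, 14 lower and 3 higher under B, and 3082 of 18315 had an unadjusted p under 0.05, where 916 would be expected by chance. They included a dim probe of Eef1a1, a translation elongation factor (log2 difference -2.18), a probe of Hadh, an enzyme of fatty acid oxidation (log2 difference -1.46), a probe of H2-K1, an MHC class I gene (-1.20), and a probe of Scg2, a granule protein (-1.36), chosen after their values were seen. No probe had a genotype by letter interaction past an adjusted p of 0.05 in limma, and 427 had an unadjusted p under 0.05. With the letter as a block, 3 probes passed for genotype, all of Sri, and Laptm4a had a limma adjusted p of 0.0887. Within letter A alone Laptm4a had a log2 fold change of -3.11 (adjusted p = 0.000575), and within letter B alone -2.18 (adjusted p = 0.884).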

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

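The tests on SRI-tg10 replicate 4, on genotype splits balanced for the title letter, on the order of columns and on the scaling and probe of Laptm4a were chosen after the results were seen, and the other tests before. Within each group of 6 arrays, a value was picked out when it stood apart from the other 5 by more than Dixon's 95% limit. Of 390 groups tested, 30 were picked out, where chance gives about 19.5. SRI-tg10 replicate 4 had 8, control replicate 5 had 7 and control replicate 2 had 5.

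SRI-tg10 replicate 4 stood apart at Sri, with 12.67, 10.10 and 12.72 at its 3 probes, and at Laptm4a with 10.21 where the other SRI-tg10 arrays reached at most 7.87. A dim array is argued against by its 18671 detected probes, within the range of the other arrays, and a swap with a control of this set by the gap between groups, since the highest control lay below the lowest SRI-tg10 array by a log2 difference of -2.05 or further at every Sri probe. A mixture with control RNA remains open: the 3 Sri probes would need shares of SRI-tg10 RNA that span 18.4 percentage points (6.45%, 17.9% and 24.8%), but 2 of the probes reach 64.6% and 88.7% of the highest signal on an array, where compression could distort the share. Laptm4a, at 2.94% of the highest signal or less, gives a share of 51.2%, with a range of 0.0254% to 70.1% over pairs of arrays that spans the Sri shares. The low end of that range rests on control replicate 5, the dimmest array, whose raw signal of 1119 equals that of SRI-tg10 replicate 4. Lower transgene expression in this mouse stays open and was not tested.

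The fall of Laptm4a kept its call without background correction (log2 fold change -2.17, limma adjusted p = 0.0203). It also kept it with median scaling in place of quantile normalization, after background correction (-2.69, adjusted p = 0.0105). This argues against either step alone as its whole source, but neither setting left out both steps. Over 26 alternatives the adjusted p ran from 4.85e-08 to 0.999, the highest with the processed values by their deposited headers. A change in the chromosomal neighbourhood may still be involved: of the 20 genes nearest to Laptm4a in the GRCm38.p6 annotation 3 were tested, with a median log2 fold change of -0.0676 and none lower at an unadjusted p under 0.05. The bound set beforehand was met, but it did not allow for so few tested neighbours: a minimum of 5 was added after that count was seen, so the explanation is left open. A sequence variant under the probe cannot be told apart from a lower transcript level, since the gene has 1 probe on the array. The raw signals of SRI-tg10 replicate 4 and of control replicate 5, the dimmest array, both read 1119, while on normalized values every SRI-tg10 array lay below every control (10.21 at most against 10.30).

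The columns of the deposited table of processed values follow the order of the signal table under accession headers. Each of the 12 correlated best with the array at the same place there (r from 0.965 to 0.996, the second best at most 0.529). How the headers came to differ was not tested. Processing that altered each array's own values is argued against by 10 columns that were closer to another array by over 0.5 in r. By its headers this table puts Sri at a log2 fold change of -0.31 between genotypes, and Sri and Laptm4a then differ between the title letters instead, at 4 probes.

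The count of 4 probes that differed by genotype was reached in 4 of 100 splits of the arrays, the real one included, under the bound set beforehand. Since 3 of these 4 probes are of the transgene Sri, the count by itself does not bear on Laptm4a. The highest other split called 320 probes, and what that split follows was not tested. Chance cannot be excluded for the 3 shifted gene lists, which 90 of 100 splits matched, with up to 17 lists in another split. The 17 probes that differed by title letter were matched by 4 of 100 balanced splits, the real one included, again under the bound. The highest other split gave 339. The interaction had 0 probes, a count that every split matches (100 of 100, the highest other 300), so the splits say nothing about it. With 3 arrays of each letter on each side, 3 of 100 splits matched the 4 probes by genotype (the highest other 327). The 3 probes with the letter as a block, all of Sri, were also matched by 3 of 100 (the highest other 440). Both counts include the real split and are under the same bound. Chance cannot be excluded for the lists, 3 and 2 with the block, which 95 and 97 of 100 splits matched with up to 17.

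SRI-tg10 replicate 4 was also low at Nkx2-2 (10.07), Calm3 (12.55), Syt7 (9.65) and Acaca (9.04), all on the log2 scale. Control replicate 5 was low at Nfatc1 (6.45), Vamp2 (8.97), Hes1 (5.49), Atp2a2 (12.30), Nkx6-1 (10.33) and the mean of the calcineurin and NFAT list (8.96), and high at the erythroid gene Alas2 (9.88). Control replicate 2 was high at Atf5 (11.66), Mafa (7.59) and the mean of the Schwann cell and neuronal list (7.22), and low at Gca (7.79) and Prlr (11.69). Control replicate 3 was high at Sesn2 (7.74) and Pgam1 (9.02), and control replicate 1 at Cela1 (14.90). SRI-tg10 replicate 6 was high at Dnajb9 (12.62) and Adrb3 (5.67) and low at Reg1 (14.22), and replicate 2 was low at Ndufs3 (10.84). SRI-tg10 replicate 3 was low at Ppy (13.65) and in detected probes (17372), and high in the mean of the NRF2 and metallothionein list (10.29).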

How the results depend on the processing

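Settings with matched columns, with the authors' probes and weights, with fry without Sri, or without both SRI-tg10 replicate 4 and control replicate 5 were chosen after seeing the data. The cause of each change below was not tested. Each letter alone leaves the same number of arrays, yet Sri kept its call in letter A alone (limma adjusted p = 8.73e-05) and lost it in letter B alone. Fewer arrays therefore do not by themselves account for the losses in letter B. By their deposited headers, 10 of 12 columns of the processed values matched another array. Sri kept its direction and call in 24 of 26 alternatives. With the processed values by their deposited headers the Sri probes had -0.31, -0.25 and -0.51, Laptm4a 0.31, no probe passed (0), 7 lists shifted, r with the deposited fold changes was -0.197, 4 probes differed by letter, and the PERK list (-0.12) and acinar list (-0.15) turned lower than other genes. Letter B alone gave Sri 4.30 (adjusted p = 0.883), 0 probes and 1 list, lymphocytes at 1.31. Over its 26 alternatives the adjusted p of Sri ran from 4.51e-12 to 0.999, the highest with the processed values by their deposited headers. Letter A alone gave 11 lists, with the lymphocyte list at -0.63. Counting genes by their brightest probe gave 1, Sri. The number of shifted lists was 0 with an estimated correlation, 1 with fry (one-way and mixed), 6 with median scaling and 8 with array weights. Without both doubted arrays, 4 probes passed and 5 lists shifted, the stromal list at -0.13. With the authors' matched values, probes and weights and without SRI-tg10 replicate 4, all changed together, 11 lists shifted, with the stromal list at -0.16 and the NF-kB list at -0.18, and r was 0.994. On leaving out each array in turn, Sri ran from 4.58 to 5.03, called probes from 3 to 5, lists from 0 (without control replicate 3) to 9 (without control replicate 5; 1 without control replicate 1, 8 without SRI-tg10 replicate 2, 5 without control replicate 6) and r from 0.666 to 0.901. The ATF6 list kept its call in 25 of 30 alternatives, the IRE1 list in 22, the macrophage list in 13, and Laptm4a in 9 of 26. Each list count includes the processed values by their deposited headers (camera adjusted p = 0.00479, 0.00245 and 0.0271 in the same order). There the headers of each genotype held arrays of both genotypes, so those list calls are no support for a genotype effect. Signals near the top of the scale limit the Sri, insulin, glucagon and somatostatin folds and those of the brightest acinar markers, and dim probes limit Ryr2. Slide as a block was not run.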

Other observations

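Genes of growth hormone and sterol pathways gave values that did not pass the test over all genes. Cish, a feedback inhibitor of STAT5 signalling, was 9.89 ± 0.41 in controls and 10.74 ± 0.55 in SRI-tg10 islets (SD, n = 6 each, log2 scale), above the control mean in 6 of 6 SRI-tg10 arrays, with a limma adjusted p of 0.922 over all genes and 0.0523 adjusted over the list alone. Of 20 tested cholesterol synthesis genes 17 were higher by sign, with Srebf2, a regulator of these genes, at 0.28 (camera adjusted p = 0.148). That list was called higher without SRI-tg10 replicate 2, SRI-tg10 replicate 4 or control replicate 5 (adjusted p = 0.0378, 0.0357 and 0.0372), and in title letter A alone (adjusted p = 0.00490). Over all 12 arrays it was called with the mean of a gene's probes (adjusted p = 0.0354) and with probes at a detection p under 0.01 on all arrays (mean relative to other genes 0.15, adjusted p = 0.0206). These calls used the preset correlation, and over all arrays it had adjusted p = 0.684 with an estimated correlation. Of 23 tested cell cycle genes 17 were lower by sign, with Cdk1 at -0.55 and Birc5 at -0.52, or -0.29 without control replicate 5 (camera adjusted p = 0.150). The mean of this list relative to other genes was -0.33 without SRI-tg10 replicate 4 (adjusted p = 0.000554), -0.31 without SRI-tg10 replicate 5 (adjusted p = 0.000819), -0.26 without control replicate 5 (adjusted p = 0.00567) and -0.63 in title letter A alone (adjusted p = 1.26e-17). It was also called with array weights (adjusted p = 3.22e-05) and with median scaling (adjusted p = 0.0183), and over all arrays it had adjusted p = 0.837 with an estimated correlation. The heat shock gene Hspa1a had 1.02 at its brightest probe, with an adjusted p of 0.922, and 0.57 and 0.50 at its other probes. All 6 SRI-tg10 arrays lay above the control mean of the brightest probe, but control replicate 2 (11.13) lay above 5 of them.

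Y-linked Ddx3y and Eif2s3y each had a probe detected on all 12 arrays. Of 4 Xist probes, 1 was detected on 4 arrays (up to 6.44 on the log2 scale), 2 on 1 array each (up to 6.98 and 6.88) and 1 on none, against at least 8.40 for those Y-linked probes.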
